A study of Drosophila melanogaster with 6 samples.

How the data were processed

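RIP-seq and input RNA-seq libraries from nuclear extracts of Drosophila melanogaster embryos were compared. Per the labels' protocols, 12 mg of nuclear extract was used for each immunoprecipitation, RNA was eluted from the beads, treated with DNase and chemically fragmented, libraries were made with a NuGEN Ovation kit, and 50 bp single-end reads were sequenced on an Illumina HiSeq instrument. Groups (input and Isha RIP, 3 libraries each) and replicate numbers were taken from the sample titles.

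The authors deposited a table of raw read counts per gene in the layout of featureCounts, with FlyBase gene identifiers, exon coordinates, strand and summed exon length. The submitters' processing notes name cutadapt 2.9, HISAT2 2.2.1, Picard 2.22.2, featureCounts, Subread 2.0.0, R 4.1.0 and DESeq2 1.32.0 and the genome build dm6. The annotation version, the strand setting, and the treatment of duplicates and of reads with several positions are not given in the sources used here. Counting reads that match several places in other ways would change the levels of rRNA, tRNA, snRNA, histone and other multicopy genes, and counting without strand would mix genes that overlap on opposite strands. Of the 17612 genes in the deposited table, exons of 1258 overlap another gene on the same strand and exons of 4584 overlap one on the opposite strand. Of the 111 genes taken by the rule for named genes, 32 have such an overlap on either strand. The authors' summed exon length per gene was used for the length offset and the length matching.

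The deposited table pairs no symbols with its identifiers. Symbols and gene types were taken from a table of RefSeq genes of the same build by an exact match of chromosome, start and end for 17189 genes and by the identifier among synonyms for 13. The other 410 (340 sharing coordinates with another gene and 70 unmatched) kept their identifiers. They held 0.0708% of counts in input and 0.0912% in RIP. Symbols of the mitochondrial genome carry no prefix in that table, so its list was taken by chromosome and its genes were kept out of the nuclear oxidative phosphorylation list. The list members mod(mdg4), calypso, glo, cup, nxf3 and Adh found no match and were left out.

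Genes were filtered with filterByExpr (minimum count 10), which left 11764, and scaled with TMM factors (0.986 to 1.01). The main test was edgeR's quasi-likelihood F-test with group as the only term and Benjamini-Hochberg adjustment over all tested genes, 2-sided, with calls at an adjusted p under 0.05. Standard errors were taken as the size of the log2 fold change over the square root of F. The common dispersion was 0.0231, a biological coefficient of variation of 0.152. CPM values are counts scaled to the library total and TMM factor, given as mean ± SD over libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Gene lists were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, with an adjustment over the 35 lists; the same test with an estimated correlation and fry were alternatives. The shift is competitive: it sets a list against all other genes.

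Before the data were examined, the test, the lists and the rule for named genes were fixed. The rule took su(Hw) and the gene of Isha; every tested insulator gene; the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 CPM and no overlap of CPM between the groups, leaving out rRNA, tRNA, snRNA and snoRNA genes; in each shifted list up to 4 called members of smallest adjusted p and up to 2 that went the other way; and the 3 genes with the highest share of counts in each group. Genes named outside this rule are said to have been chosen after their values were seen.

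Replicate libraries were compared before averaging. All 6 pairs within groups differed beyond counting noise (chi-square over degrees of freedom 5.78 to 14.3). Each library was counted as 1 replicate, but such a difference does not show that libraries came from separate extracts. The input libraries were on average 2.94 times as deep as the RIP libraries, which limits low-abundance transcripts in RIP: 3 counts correspond to 0.209 to 0.358 CPM in a RIP library and 0.0947 to 0.102 CPM in an input library. Among tested genes 15 had 0 counts in all RIP libraries and 2 had 0 in all input libraries, so their fitted fold changes are not bounds and are not given. Floors and the interval of the rRNA pseudogene ratio cover counting error only, and bootstrap intervals cover the spread between genes.

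The workflow was tested on simulated counts drawn for the real genes and library sizes. For Isha RIP against input, with 11638 simulated genes tested by edgeR, 34% of genes changed 1.25-fold were recovered, 42% of those changed 1.5-fold, 68% of those changed 2-fold and 90% of those changed 4-fold, with 50 genes of each, and 6 unchanged genes were called. All 5 lists shifted 1.5-fold were called by camera and 0 of 40 unchanged lists were. Simulated genes were drawn independently and only the chosen genes changed. The simulation therefore does not show how often camera errs where genes are correlated or most genes change.

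Alternatives covered scaling (RLE, upper quartile, library totals), removal of small structural and mitochondrial genes, DESeq2, limma-voom, no filter and a strict filter on counts, the replicate number as a block, a gene length offset with and without the block, robust dispersion, each library left out, an adjusted p under 0.01 and a test against a 1.5-fold change. After the data were seen, thinning to equal depth, leaving out overlapping genes and centring on protein-coding genes were added. Base composition was not tested, since no genome sequence was used here.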

Results

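RNA immunoprecipitation followed by sequencing (RIP-seq) was used to ask which transcripts, su(Hw) among them, are recovered with the protein Isha in vivo in the fruit fly Drosophila melanogaster. Nuclear extract came from wild-type Oregon R embryos of mixed stages, 0 to 24 h old. In the Isha RIP group, RNA was taken from beads carrying rabbit antiserum against Isha, after the extract had been precleared on beads carrying preimmune serum. The input group was sequenced from the same kind of extract without immunoprecipitation. Each group had 3 libraries. The total count per library was 29344529 to 31680173 in input and 8386414 to 14342543 in Isha RIP. Levels are given as CPM, the count scaled to the library total and TMM factor. By library total alone, 1 count was worth 0.0316 to 0.0341 CPM in input and 0.0697 to 0.119 CPM in RIP. Among the 7723 genes with a mean of at least 10 CPM, the median coefficient of variation of CPM between libraries was 6.23% in input and 9.07% in RIP. The labels do not say that the 3 libraries of a group came from separate embryo collections, so p-values measure the spread between these libraries, which may be technical.

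The Isha RIP libraries held more protein-coding and long noncoding RNA and less small nuclear and nucleolar RNA than input. Protein-coding genes took 89.5% ± 0.231 (SD, n = 3) of counts in input and 95.2% ± 0.0248 in RIP. Long noncoding and antisense RNAs took 1.05% ± 0.0106 in input and 2.01% ± 0.0258 in RIP. Small nuclear RNAs (snRNAs) took 3.48% ± 0.250 in input and 0.173% ± 0.0124 in RIP, and small nucleolar and Cajal body RNAs (snoRNAs and scaRNAs) took 4.88% ± 0.0993 and 2.06% ± 0.0486. Of the snRNA share, 7SK RNA (snRNA:7SKa), a regulator of the elongation factor P-TEFb, held 2.81% ± 0.222 in input and 0.117% ± 0.00755 in RIP. The most abundant transcripts in RIP were apolpp, the precursor of the main hemolymph lipoprotein, at 17090 CPM ± 255 against 10368 ± 151 in input, bnb at 5564 CPM ± 137 against 3700 ± 123, and the translation factor eEF1alpha1 at 5185 CPM ± 21.6 against 4706 ± 138. In input the most abundant were snRNA:7SKa at 28399 CPM ± 2351, apolpp, and snoRNA:Psi18S-1820 at 8046 CPM ± 542. Exons of apolpp overlap those of Zyx on the opposite strand.

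The first comparison asked which transcripts were enriched with Isha over input. Of 11764 genes tested, 3176 were enriched and 3573 were depleted in RIP at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and 5015 did not pass. Enrichment of at least 2-fold was found for 1015 genes and depletion of at least 2-fold for 1510. The median log2 fold change of all tested genes was -0.05, and the middle 90% of genes lay between -1.66 and 1.44, which are the percentiles 5 and 95. CPM values of the groups did not overlap in 7525 of the 11764 tested genes, where chance gives 10% for 3 libraries against 3. With a test against a 1.5-fold change, 1345 genes were enriched and 1703 depleted. All changes are relative to input: a control immunoprecipitation was not analysed here, so recovery with Isha and recovery with beads or serum are not told apart. Each library was scaled to its own total and TMM factor, so a median near 0 with calls in both directions was largely built in. Enriched and depleted therefore mean above or below the typical transcript, and these counts do not give the amount of RNA recovered.

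**Figure D1:**
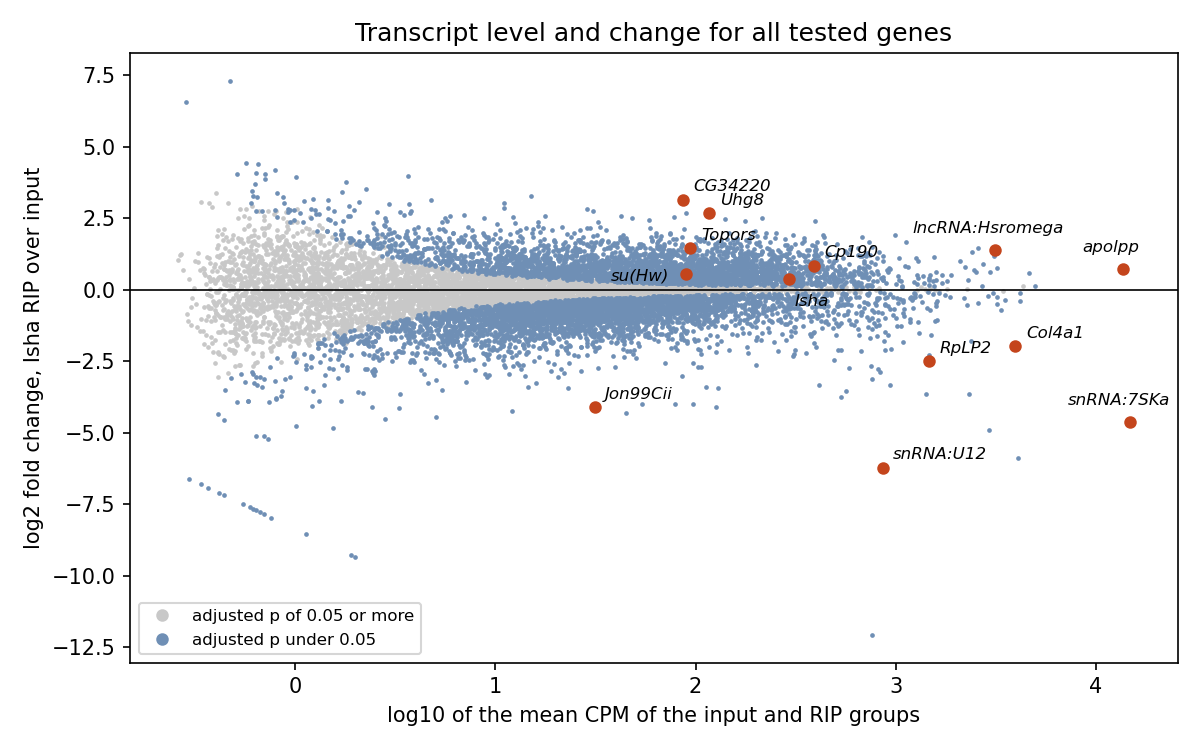
Log2 fold change of Isha RIP over input (vertical axis) against the log10 of the mean CPM of both groups (horizontal axis) for the 11764 tested genes, with called genes in blue, others in grey and named genes in orange. su(Hw) lies at 0.53 and Isha at 0.36, within the bulk of called genes, while snRNA:U12 lies at -6.22 and CG34220 at 3.14.

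su(Hw), the zinc-finger DNA-binding protein of the gypsy insulator and the transcript named in the study's design, was enriched in Isha RIP. It was measured at 73.5 CPM ± 4.24 (SD, n = 3) in input and 105.9 CPM ± 1.49 in RIP, a 1.44-fold difference, with all 3 RIP libraries above all 3 input libraries. Its raw counts were 2314, 2003 and 2424 in input and 944, 899 and 1504 in RIP. The log2 fold change was 0.53 with a standard error of 0.079 and an adjusted p of 4.66e-06 (edgeR). By size of log2 fold change su(Hw) ranked 2919 of the 11764 tested genes, at percentile 75.2, and it was not among the genes enriched at least 2-fold. The gene (FBgn0003567) lies on chromosome 3R from 14304455 to 14308589 on the minus strand of dm6, with a summed exon length of 3682 bases. Its exons overlap those of IFT54 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of IFT54 may be counted in it.

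The transcript of Isha itself was also higher in RIP, at 256 CPM ± 2.224 (SD, n = 3) in input and 328 CPM ± 5.29 in RIP. Its log2 fold change was 0.36 with a standard error of 0.050 and an adjusted p of 1.60e-06 (edgeR), a 1.28-fold difference that ranked 3740. Under 21 alternatives the transcript of Isha stayed enriched, at log2 fold changes of 0.22 to 0.40. Raw counts of Isha were 7874, 7519 and 8074 in input and 2941, 2776 and 4661 in RIP. The gene (FBgn0034598) lies on chromosome 2R from 21161713 to 21168659 on the minus strand, and no other gene's exons overlap it.

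Transcripts of insulator proteins and their partners went both ways. Of 22 tested members, with su(Hw) and Isha among them, 12 were enriched, 5 were depleted and 5 did not pass, and the counts adjusted over the list alone were the same 12 and 5. The largest enrichments were of Topors, a ubiquitin ligase that binds gypsy insulator proteins, from 50.5 CPM ± 4.62 to 138 ± 5.69 (SD, n = 3), and of the RNA-binding protein shep, from 143 CPM ± 3.68 to 374.5 ± 25.5. The zinc-finger protein ZIPIC rose from 14.6 CPM ± 3.32 to 33.2 ± 0.803. Cp190, a cofactor shared by several insulator complexes, rose from 280 CPM ± 16.4 to 497 ± 5.45, a 1.78-fold difference and thus above that of su(Hw). Ibf2 rose by 0.93 on the log2 scale, AGO2 by 0.51 and CTCF by 0.49. The depleted members were pita, from 44.9 CPM ± 4.86 to 23.9 ± 4.57, rump at a log2 fold change of -0.44, dwg at -0.42, Chro at -0.34 and pzg at -0.21. HIPP1, Clamp and Rm62 passed with log2 fold changes of 0.26, 0.22 and 0.12. Values for the members that did not pass were 0.51 for e(y)2, 0.19 for M1BP, 0.18 for Trl, 0.04 for Ibf1 and -0.16 for BEAF-32, and those of Trl, Ibf1 and BEAF-32 changed sign under some alternatives (to -0.03, -0.07 and 0.08 at most). As a set the list was not shifted against other genes (median log2 fold change 0.24, camera adjusted p = 0.062, and 0.165 with an estimated correlation). It was called without a count filter (camera adjusted p = 0.0335) and by fry (0.000139), which does not compare it with other genes. M1BP passed with a gene length offset (log2 fold change 0.46). The call of dwg, with an adjusted p of 0.0494 (edgeR), was lost under 13 of 21 alternatives, and Rm62 turned to a log2 fold change of -0.05 with a gene length offset. HIPP1 lost its call without input replicate 1 or RIP replicate 2 (log2 fold changes 0.21 and 0.17), and Clamp lost its call without input replicate 1 or 3 or RIP replicate 1 or 3 (0.18 to 0.19). Exons of 12 of the 22 genes overlap another gene, namely su(Hw), Cp190, ZIPIC, AGO2, CTCF, Clamp, e(y)2, Trl, BEAF-32, pita, rump and Chro.

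**Figure D2:**
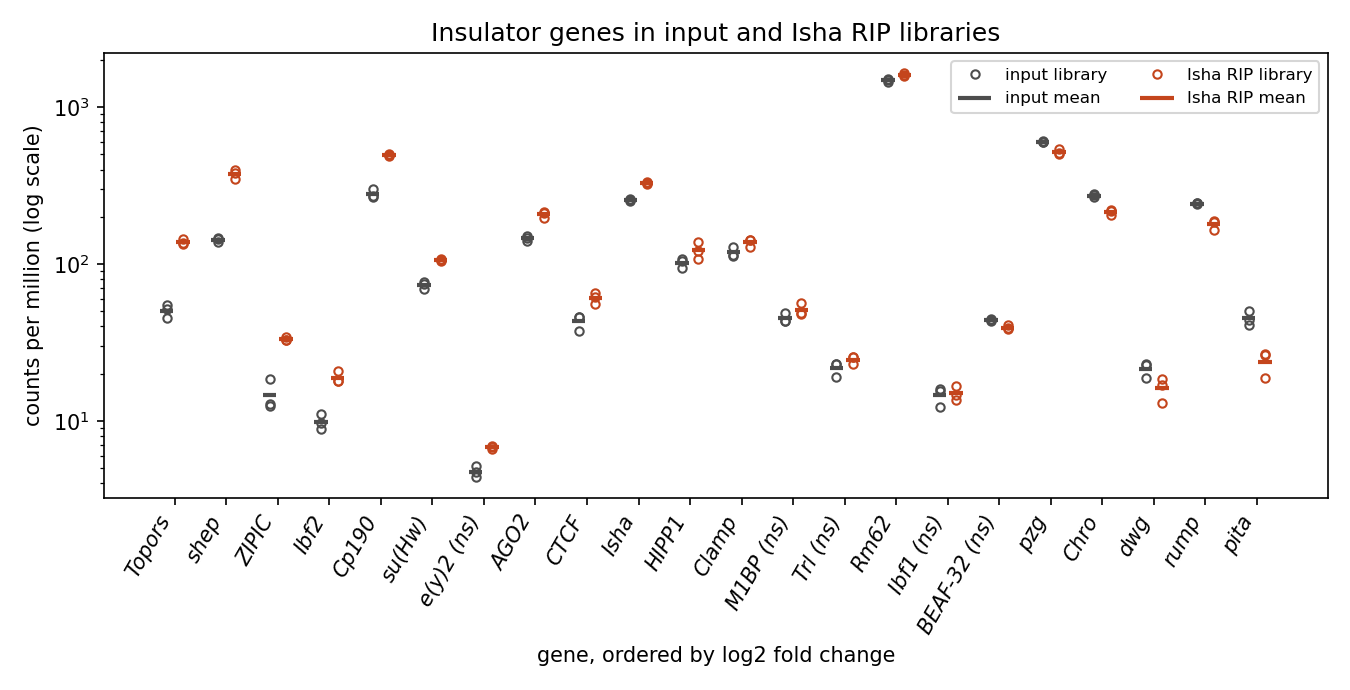
CPM on a log axis for the 22 tested insulator genes, ordered by log2 fold change, with circles for the 3 libraries of each group and bars for their means; (ns) marks an adjusted p of 0.05 or more. Topors, shep and ZIPIC at the left differ more than 2-fold, su(Hw) differs 1.44-fold, and pita at the right is lower in all 3 RIP libraries.

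The largest enrichments among genes of at least 10 CPM were of noncoding RNAs and some coding genes. lncRNA:CR44973 was measured at 2.81 CPM ± 0.912 (SD, n = 3) in input and 27.2 ± 6.90 in RIP, a 9.61-fold difference. CG34220, a coding gene, rose from 17.6 CPM ± 1.99 to 156 ± 15.8, and CG15480 from 24.0 CPM ± 1.08 to 155 ± 4.62. The snoRNA host transcript Uhg8 rose from 31.9 CPM ± 1.36 to 202 ± 8.18. Among early zygotic genes, halo, which acts in lipid droplet transport, rose from 7.96 CPM ± 1.48 to 53.5 ± 5.95, and Z600, an inhibitor of mitosis, from 5.06 CPM ± 0.438 to 30.4 ± 2.23. Ing5, of a family of chromatin readers, rose from 22.8 CPM ± 1.29 to 133 ± 12.1. The other members of the 12 largest were lncRNA:CR44138, asRNA:CR43933, lncRNA:CR45938, lncRNA:CR44417 and sisRNA:CR46360, at log2 fold changes of 2.54 to 3.01. Exons of asRNA:CR43933, Uhg8 and Z600 overlap other genes, so their reads are uncertain.

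The largest depletions included gut serine proteases, mitochondrial proteins and small structural RNAs. The protease genes Jon99Cii and Jon99Fi fell from 59.3 CPM ± 11.3 to 3.42 ± 0.479 (SD, n = 3) and from 42.1 CPM ± 3.03 to 3.85 ± 1.63. They are members of a multigene family, so reads could be split between copies. The noncoding sncRNA:CR43603 fell from 149 CPM ± 7.63 to 9.05 ± 2.93, and the RNA of RNase P (RNaseP:RNA), which trims tRNA precursors, from 1419 CPM ± 13.4 to 208 ± 15.9. Among mitochondrial proteins, NdufA3 of respiratory complex I was 10.5-fold lower, Lrpprc2 8.19-fold and mRpL2 7.13-fold. SmB, a core protein of spliceosomal snRNPs, fell from 36.9 CPM ± 5.03 to 5.63 ± 2.30. Dus2, CG9757, Npc2g and CG4229 completed the 12, at log2 fold changes of -3.26, -2.91, -2.86 and -2.78. The log2 fold change of NdufA3 was -3.40, and -4.03 without RIP replicate 2; that of CG4229 was -3.37 without RIP replicate 1. Exons of mRpL2 overlap those of Ufd1.

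The second comparison asked whether gene groups fixed in advance shifted together. Of 35 lists tested, 13 were shifted against other genes, 5 up and 8 down (camera, preset correlation, adjusted p under 0.05), and 6 of these 13 were also called with an estimated correlation. Transcripts of RNA-binding proteins and of neurons were enriched. Of 35 hnRNP and RNA-binding protein genes, 26 rose and 5 fell, also when adjusted over the list alone, with a median log2 fold change of 0.58 (camera adjusted p = 4.17e-08, and 0.041 with an estimated correlation). Pasilla (ps), a splicing regulator, rose from 406 CPM ± 2.15 to 920 ± 29.2 (SD, n = 3), nonA from 162 CPM ± 3.35 to 430 ± 12.0, and the translational repressor me31B from 126 CPM ± 4.99 to 298 ± 20.7, while the germline regulator nanos fell from 19.8 CPM ± 2.49 to 7.45 ± 2.19. Of 28 neuron markers, 22 rose and 2 fell, again with the same counts adjusted over the list alone, and the median was 0.58 (camera adjusted p = 4.21e-07, and 0.044 with an estimated correlation). The potassium channel gene Sh rose from 74.4 CPM ± 1.35 to 192 ± 0.868, the synaptic vesicle gene nSyb from 166 CPM ± 13.6 to 384 ± 11.4, cpo from 306 CPM ± 15.8 to 618 ± 21.4 and scrt from 104 CPM ± 3.23 to 229 ± 8.31. The 2 neuron-list genes that fell were mira at a log2 fold change of -0.70 and dpn at -0.95. The gene ase, which like mira and dpn acts in neural stem cells and was named after its values were seen, rose from 13.6 CPM ± 1.63 to 30.9 ± 3.49. With a gene length offset the neuron list was still called but its median was 0.37 (camera adjusted p = 0.00602), with Sh at 0.98 and cpo at 0.70, and without overlapping genes the median was 0.90. Among coding genes the median log2 fold change was 0.21 for exon lengths above 4000 bases and -0.08 for 2000 to 4000 bases. It was lowest, at -0.30, for 1000 to 2000 bases, with -0.24 for 500 to 1000 and -0.17 up to 500. The median thus did not fall steadily with shorter length. The genes elav, fne and Rbp9 belong to both lists. Exons of nanos and dpn overlap other genes.

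Long noncoding RNAs were shifted up as a class in the main test. Of 675 tested genes annotated as lncRNA, antisense RNA or CR, 181 rose and 21 fell (143 and 16 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.0167, and 0.029 with an estimated correlation). DESeq2 and the fit without a count filter did not call this shift (camera adjusted p = 0.219 and 0.0731), and the median was 0.43 without the filter. Of all tested genes 27.0% were enriched and 30.4% depleted. The share of this class that rose was close to the former, and the class differed in how few of its genes were called as falling. RIP libraries were less deep, and a fall leaves fewer RIP counts to test. Whether low counts limited the falls called in this class was not tested. lncRNA:Hsromega, the scaffold of nuclear omega speckles, rose from 1733 CPM ± 28.3 to 4557 ± 105 (SD, n = 3), lncRNA:CR43334 from 330 CPM ± 11.3 to 809 ± 24.7 and lncRNA:CR43651 from 218 CPM ± 10.8 to 572 ± 10.9. lncRNA:CR34335 went the other way, from 303 CPM ± 38.9 to 65.2 ± 8.77, as did lncRNA:alphagamma-element:CR32865 at a log2 fold change of -1.79. Of 11 nuclear long noncoding RNAs fixed by name, 8 rose and 1 fell with a median of 0.92 (camera adjusted p = 0.000419, but 0.0773 with an estimated correlation). Uhg5, a snoRNA host, rose from 126 CPM ± 9.22 to 664 ± 33.6, and the member that fell was snRNA:7SKa, at a log2 fold change of -4.62. Of 8 dosage compensation genes, 6 rose and 1 fell with a median of 0.38 (camera adjusted p = 0.0273, but 0.165 with an estimated correlation). The roX RNAs that coat the male X chromosome both rose, lncRNA:roX1 from 1632 CPM ± 20.2 to 2793 ± 12.3 and lncRNA:roX2 from 78.4 CPM ± 6.90 to 216 ± 3.11. In this list msl-1 and msl-2 rose by 0.73 and 0.47 on the log2 scale, and mle, a helicase, had a log2 fold change of -0.26 whose call was lost without input replicate 1 or RIP replicate 1 (-0.20 and -0.18) or after thinning to equal depth (-0.20). Leaving out genes with overlapping exons ended the call of both lists (adjusted p = 0.256 for nuclear long noncoding RNAs and 0.202 for dosage compensation), and a strict count filter that of dosage compensation (0.0518). In both of these lists the counts adjusted over the list alone were the same. Both roX RNAs belong to the lncRNA class, the nuclear long noncoding RNAs and the dosage compensation list. lncRNA:Hsromega is in the first and second of these, and snRNA:7SKa is also in the snRNA list. The shifts of these lists are therefore not separate findings. Exons of lncRNA:roX1 and lncRNA:CR43334 overlap other genes.

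The snRNAs were depleted, while snoRNAs, scaRNAs and rRNA genes and pseudogenes went both ways, with more falls than rises. Of 21 snRNA genes, 16 fell and 0 rose (edgeR; 0 rose at an unadjusted p under 0.05 or by DESeq2 or limma-voom), with a median of -2.43 (camera adjusted p = 1.65e-20, and 0.0283 with an estimated correlation), or -3.31 with a strict count filter. U12 and U11 of the minor spliceosome fell from 1699 CPM ± 254 to 22.4 ± 3.14 (snRNA:U12; SD, n = 3) and from 2620 CPM ± 61.4 to 209 ± 22.2 (snRNA:U11), and snRNA:U4:39B from 994 CPM ± 51.7 to 72.6 ± 9.93. Of 216 snoRNAs and scaRNAs, 92 fell and 32 rose, with a median of -0.37 (camera adjusted p = 4.17e-08, but 0.0773 with an estimated correlation). snoRNA:Psi18S-1820 fell from 8046 CPM ± 542 to 137 ± 6.54 and snoRNA:Psi28S-291 from 5675 CPM ± 261 to 188 ± 21.5. In the other direction snoRNA:Psi28S-1192b rose from 73.7 CPM ± 3.94 to 250 ± 12.8 and snoRNA:Me28S-G2017 from 18.6 CPM ± 3.42 to 99.2 ± 1.76. For the snRNA and snoRNA lists the counts adjusted over the list alone were the same. Of 10 tested rRNA genes and pseudogenes, 4 fell and 1 rose, also over the list alone (median -0.78, camera adjusted p = 0.000373, but 0.113 with an estimated correlation). DESeq2, limma-voom and the fit without a count filter did not call that shift (adjusted p = 0.183, 0.557 and 0.176), and the list median was -0.48 without input replicate 3 and -1.47, -1.71 and -1.79 without RIP replicates 1, 2 and 3. The pseudogene 28SrRNA-Psi:CR41609 had 49104, 42582 and 47446 counts in input and 2, 2 and 7 in RIP, a ratio of 4302 after scaling to library totals (95% interval of the counting error 2404 to 8617). 18SrRNA-Psi:CR41602 had 19.4 CPM ± 23.2 in input, and its log2 fold change of -2.71 became -1.02 without input replicate 1. Its call was lost with limma-voom and robust dispersion (adjusted p = 0.118 and 0.125), and that of 5SrRNA-Psi:CR33363, also among the 4 that fell, with limma-voom and without input replicate 2 or 3 or RIP replicate 1 (0.0504 to 0.0879). rRNA copies are near identical, so their counts are uncertain.

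Transcripts of ribosomal proteins, respiratory chain subunits and nuclear pore proteins were depleted. Of 82 cytoplasmic ribosomal protein genes, 66 fell and 7 rose (68 and 7 adjusted over the list alone), with a median log2 fold change of -0.95 (camera adjusted p = 2.51e-43, and 0.040 with an estimated correlation). RpLP2 fell from 2496 CPM ± 46.1 to 441 ± 13.8 (SD, n = 3), RpL8 from 1303 CPM ± 60.8 to 202 ± 19.98, and RpS2 from 1945 CPM ± 25.7 to 675 ± 17.7. RpS27A and RpL15 went the other way, from 657 CPM ± 14.8 to 967 ± 30.8 and from 1226 CPM ± 25.5 to 1733 ± 76.6, and the exons of both overlap another gene. Of 65 nuclear genes of oxidative phosphorylation, 42 fell and 9 rose (42 and 10 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 8.60e-07, and 0.0297 with an estimated correlation). The Rieske protein gene RFeSP fell from 166 CPM ± 11.3 to 39.6 ± 4.23, ATPsyngamma from 112 CPM ± 6.08 to 33.9 ± 0.911 and ND-39 from 117 CPM ± 8.36 to 35.3 ± 3.11, while COX7B rose from 149 CPM ± 4.21 to 226 ± 18.2. Of 72 mitochondrial ribosomal protein genes, 36 fell and 3 rose, also over the list alone, with a median of -0.51 (camera adjusted p = 0.0196, but 0.0840 with an estimated correlation). mRpS22 fell from 53.8 CPM ± 3.31 to 22.2 ± 3.26 and mRpL12 from 46.5 CPM ± 5.98 to 19.5 ± 2.66, while mRpS5 rose from 36.3 CPM ± 1.58 to 75.4 ± 6.96. The call of this list also ended with a gene length offset and replicate block together (adjusted p = 0.0556) and without overlapping genes (0.329). Of 27 nuclear pore genes, 22 fell and 0 rose, also over the list alone (edgeR; 0 rose at an unadjusted p under 0.05 or by DESeq2 or limma-voom), with a median of -0.70 (camera adjusted p = 0.00164, but 0.113 with an estimated correlation). Sec13 fell from 96.2 CPM ± 9.11 to 42.1 ± 2.65, Ndc1 from 56.6 CPM ± 4.84 to 25.2 ± 2.54, and Nup205 from 112 CPM ± 6.72 to 58.7 ± 7.90. Exons of RFeSP, mRpS22 and Ndc1 overlap other genes.

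Markers of blood cells and fat body split. Of 26 hemocyte and fat body genes, 14 fell and 6 rose, also over the list alone, with a median of -0.22 (camera adjusted p = 0.00235, but 0.0773 with an estimated correlation). The collagen IV genes Col4a1 and vkg fell from 6317 CPM ± 104 to 1609 ± 2.24 (SD, n = 3) and from 3664 CPM ± 94.0 to 1066 ± 27.2, and the extracellular matrix genes Pxn and Ppn fell by 1.53 and 0.70 on the log2 scale. The lipoprotein gene apolpp rose from 10368 CPM ± 151 to 17090 ± 255 and Glt from 1392 CPM ± 59.96 to 2774 ± 91.5. Under 20 alternatives the log2 fold change of apolpp lay between 0.40 and 0.76, against 0.72 in the main test. The list median was -0.15 without RIP replicate 2, -0.37 with a gene length offset and -0.40 without overlapping genes. Exons of Pxn, apolpp and Glt overlap other genes.

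**Figure D3:**
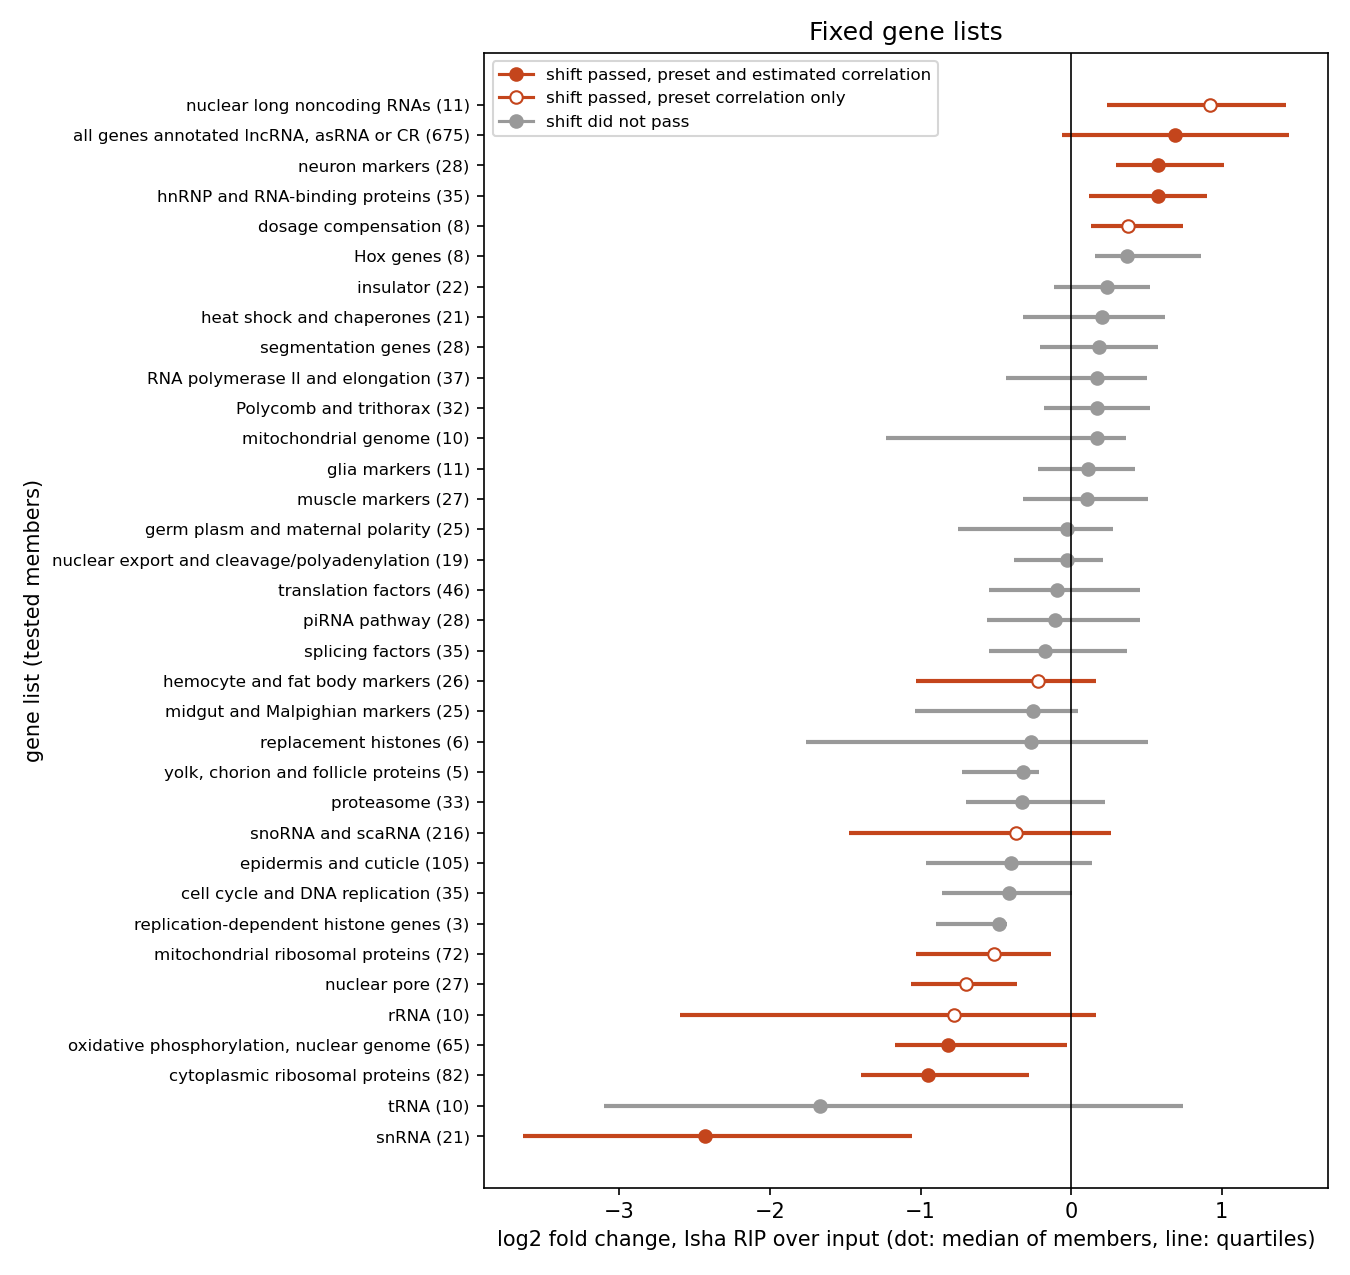
Median log2 fold change of Isha RIP over input (dots) with quartiles (lines) for the 35 fixed lists, with the number of tested members in parentheses; orange lists passed camera, and open dots mark lists that did not pass with an estimated correlation. The nuclear long noncoding RNAs lie highest at 0.92 and the snRNAs lowest at -2.43.

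The other lists did not pass the set test, though many of their genes changed. For the developmental lists, 12 segmentation genes rose and 4 fell of 28 (camera adjusted p = 0.0798), 4 Hox genes rose and 1 fell of 8 (0.121), 13 muscle markers rose and 10 fell of 27 (0.0972), 3 glia markers rose and 3 fell of 11 (0.787), 20 epidermis and cuticle genes rose and 41 fell of 105 (0.0572), and 3 midgut and Malpighian tubule markers rose and 10 fell of 25 (0.250). In the maternal and germline lists, 8 germ plasm and polarity genes rose and 6 fell of 25 (0.80), 6 piRNA pathway genes rose and 4 fell of 28 (0.927), and 0 of 5 yolk, chorion and follicle genes passed in either direction (0.801; with edgeR 1 fell at an unadjusted p under 0.05, with limma-voom 1 fell, and with DESeq2 0 passed). Adjusted over the list alone, the counts differed for the Hox genes (5 and 1) and the glia markers (4 and 3) and were the same for the other lists of these groups. Of the chromatin and RNA lists, 13 Polycomb and trithorax genes rose and 6 fell of 32 (0.0573; 13 and 8 over the list alone), 14 RNA polymerase II and elongation genes rose and 13 fell of 37 (0.311; 15 and 14), 12 splicing factors rose and 17 fell of 35 (0.885; 12 and 17), and 4 nuclear export and cleavage/polyadenylation genes rose and 5 fell of 19 (0.80; 3 and 4). Replacement histones had 3 genes up and 3 down of 6 (0.194; 3 and 3), and 0 of 3 replication-dependent histone genes passed in either direction with edgeR, at an unadjusted p under 0.05, or by DESeq2 or limma-voom (0.885; 0 and 0 over the list alone). Among housekeeping lists, 17 translation factors rose and 19 fell of 46 (0.927; 17 and 19), 7 proteasome genes rose and 17 fell of 33 (0.224; 7 and 17), 8 heat shock and chaperone genes rose and 7 fell of 21 (0.629; 8 and 7), and 5 cell cycle and replication genes rose and 18 fell of 35 (0.0701; 5 and 18). Of 10 tested tRNA genes, 4 fell and 0 rose with edgeR (camera adjusted p = 0.653; 2 and 0 over the list alone; 1 rose at an unadjusted p under 0.05, by DESeq2 and by limma-voom), with a median of -1.67, or -1.56 with tRNA:Glu-TTC-1-3, named after its values were seen and at 0 counts in RIP, set to its bound of 3 counts over the group. The tRNA median is not settled in size, from -3.08 without a count filter to -0.44 without input replicate 2. Of 10 genes of the mitochondrial genome, 3 rose and 4 fell (0.273; 3 and 4). For the mitochondrial genome the median was 0.17 and the test pointed down. This median has no settled direction, at -0.23 with DESeq2, -0.11 with limma-voom, -1.56 without a count filter, and -0.09, -0.31 and -0.15 without input replicate 1, RIP replicate 1 and RIP replicate 2. Without overlapping genes it was -0.93 and the list was called (camera adjusted p = 0.0379). For translation factors, splicing factors, nuclear export, germ plasm and piRNA genes the median and mean lay below 0 and the test pointed up. Medians of translation factors, nuclear export and germ plasm genes rose above 0 under some alternatives (to 0.12, 0.09 and 0.08 at most), and those of Polycomb and trithorax genes, RNA polymerase II and elongation genes, replacement histones and yolk, chorion and follicle genes also changed sign under some. Camera called some of these lists under other settings. Epidermis and cuticle genes were called down with upper-quartile factors, with small structural RNA and mitochondrial genes removed, without a count filter, with the replicate block, without input replicate 2 and without overlapping genes (adjusted p = 0.0276 to 0.0494). Polycomb and trithorax genes were called up with RLE factors, library totals and DESeq2 (0.0423, 0.0491 and 0.0213), segmentation genes up without a count filter (0.0335), muscle markers up with DESeq2 (0.0160), and cell cycle genes down with limma-voom and without a count filter (0.0245 and 0.0172).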

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

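Thinning to equal depth, leaving out overlapping genes and centring on protein-coding genes were chosen after seeing the data. su(Hw) stayed enriched under all 20 alternatives that tested it, with log2 fold changes of 0.48 to 0.57 and an adjusted p of at most 0.00014, and ranged from 0.48 to 0.56 with each library left out. With each library left out in turn, 2908 to 3034 genes were enriched, 3204 to 3533 depleted, 951 to 1005 enriched at least 2-fold, 1400 to 1612 depleted at least 2-fold, and 13 to 14 lists were shifted. The test against a 1.5-fold change called 1345 genes enriched and 1703 depleted, as its stricter null requires. Leaving out genes with overlapping exons left 7670 genes to test, and with fewer genes 2053 were enriched, 2343 depleted, 665 enriched at least 2-fold and 1002 depleted at least 2-fold; 4346 of the 4423 main calls among them were kept in the same direction, but su(Hw), which overlaps IFT54, was not tested there. An estimated correlation called 6 lists, and fry, which does not compare a list with other genes, called 29 for a direction and 33 for change in either direction, against 13. With a gene length offset Rm62 turned from 0.12 to -0.0541 with and without the replicate block; the cause was not tested. The lists of cytoplasmic ribosomal proteins, oxidative phosphorylation, RNA-binding proteins, neuron markers and snRNAs were called under every alternative that tested them. Of the values of single named genes under alternatives, 2229 kept call and direction or stayed uncalled in either direction, 28 lost the call in the same direction, 2 gained it and 2 of a called gene turned; of the list values, 759 were kept or stayed uncalled in this sense, 17 lost the call and 51 gained it. Of the 6749 calls, the test against a 1.5-fold change kept 3048, the gene length offset 5881 and the offset with the replicate block 5802, and each offset turned 17 to a call the other way. Scaling alone moved the median of all genes from -0.05 to between -0.10 (upper quartile) and -0.01 (RLE), and the enriched share of calls from 47.1% to between 44.2% and 49.7%.

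Replicate numbers showed no sign of pairing the libraries: correlations of deviations between same-numbered input and RIP libraries were -0.01, -0.05 and -0.01. These were taken over all tested genes, where the noise of low counts can hide a shared signal, so pairing is not excluded. With the replicate block 3065 genes were enriched and 3520 depleted, with 14 lists, and su(Hw) had a log2 fold change of 0.53. The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, the only 1 with results as large, called 6749 genes, 2525 of them at 2-fold or more, and 13 lists, and the highest of the other splits called 0 genes, 0 at 2-fold and 10 lists. Each other split mixes input with RIP libraries, which moves their difference into the spread within groups. Few gene calls there were therefore built in, and the lists called there can carry what is left of that difference. RIP depth limits low-abundance transcripts most: after thinning each library to the smallest total, 10733 genes could be tested, with 3240 enriched and 3309 depleted.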

Other observations

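Genes on chromosome 4, and the genes named from it here, were looked at after their values were seen; the tests in this part were fixed before their results were known, except the comparison of nested with other snoRNAs, and thinning to equal depth was itself chosen after the data were seen. Transcripts of the small chromosome 4 were enriched with Isha more often than those of other arms. Of its 99 tested genes, 76 were enriched and 6 depleted (edgeR, adjusted p under 0.05), 45 of them enriched at least 2-fold, with a median log2 fold change of 1.00. The medians of chromosome arms 2L, 2R, 3L, 3R and X were -0.08, -0.06, 0.0016, -0.09 and -0.10, and 24.8% to 29.2% of their genes were enriched against 76.8% on chromosome 4. The growth factor gene mav rose from 56.7 CPM ± 5.45 to 297 ± 15.2 (SD, n = 3), the calcium-dependent kinase CaMKII from 295 CPM ± 15.8 to 1055 ± 69.4, Ephrin from 154 CPM ± 2.05 to 539.5 ± 37.7, the exocytosis gene Cadps from 193 CPM ± 11.6 to 685 ± 7.08, the adaptor gene Crk from 219 CPM ± 8.96 to 671 ± 32.7, and the nucleic acid binding protein gene Pur-alpha from 59.9 CPM ± 7.92 to 234 ± 11.1. The abundant transcripts apolpp and bt also lie there and rose by 0.72 and 0.88 on the log2 scale. Exons of apolpp overlap those of Zyx. On the X chromosome, where both roX RNAs lie and rose, 519 genes were enriched and 627 depleted of 1896.

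The chromosome 4 shift was set against gene properties. Its median exceeded that of random sets of genes from other arms, matched on exon length and mean CPM, by 0.857 (matched median 0.15, central 95% of 10000 sets -0.04 to 0.31, permutation p = 1e-04, the smallest these sets can give), which argues against length and level as the whole cause. How close the matched genes came in length and CPM was not checked. Among genes with no exon overlap, the 62 on chromosome 4 lay 1.01 above the 7596 on other arms. The 95% bootstrap interval of the difference was 0.83 to 1.16, with only the chromosome 4 genes resampled. This argues against reads of genes with overlapping exons, while overlap with introns of other genes was not tested. Base composition was not tested and stays open, as does recovery on beads or serum without Isha. No biological explanation was tested.

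Small noncoding RNAs were lower in RIP, with a median of -0.49 over 241 genes of 46 to 511 bases, and a loss of short RNAs would leave the longer ones less depleted. Across these genes, which are not independent replicates, log2 fold change fell with length (Spearman rho -0.272, permutation p = 1e-04, the smallest possible). The test pooled different classes of RNA, and reads of host genes could hide a loss in short nested snoRNAs. It therefore does not decide on a loss by length. Reads of host genes could mask a loss in the 198 snoRNAs nested in 80 host genes (27 rose, 84 fell). Their median was -0.38, against -0.06 for the 18 with no host found among the tested genes (difference -0.31, 95% bootstrap interval -0.92 to 1.07). Those 18 may lie in genes that were not tested, and the interval spans 0, so this comparison does not decide. Nested snoRNAs had a rho of 0.133 in log2 fold change with their hosts (95% bootstrap interval over hosts -0.08 to 0.33, permutation p = 0.194), so masking by host reads stays open. A true absence of these RNAs from Isha complexes was not tested apart from handling that differed between input and RIP.

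Ribosomal protein transcripts lay 0.886 lower on the log2 scale than coding genes matched on exon length and mean CPM (difference -0.886, permutation p = 1e-04, the smallest possible, 82 genes). The nearest other coding genes were used, and how close they came in length and CPM was not checked. The difference argues against length and level as the whole cause only as far as the match holds. After thinning to equal depth the median of 81 genes was -0.945 (95% bootstrap interval -1.13 to -0.62). Random thinning keeps the expected ratio of CPM, and most of these transcripts are abundant, so the median could hardly move. The result therefore does not decide on the lower depth of RIP libraries. Base composition, a cytoplasmic source of these transcripts in the extract and a lower affinity for Isha were not tested, and each stays open.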
